A study of Homo sapiens with 13 samples.

How the data were processed

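Expression was measured in IMR-32 neuroblastoma cells on Affymetrix Human Genome U133 Plus 2.0 arrays, 1 sample per array and 13 arrays in all. Per the labels, cells were cultured for 24 h in 6 cm plates and transfected by lipofection with 5.5 µg of siRNA. The siRNAs targeted GFP, CCND1 (nucleotides 671 to 691) or CDK4 (nucleotides 1062 to 1082), and RNA was taken at 0 h or 48 h, with 4 µg labelled for each array. Groups were taken from the sample labels: 3 untreated arrays at 0 h, and at 48 h 4 with GFP, 3 with CCND1 and 3 with CDK4 siRNA. The GFP group held replicates 1 to 4, the CCND1 group 1, 3 and 4, and the CDK4 group 2, 3 and 4.

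The deposited values are MAS5 signal intensity on the linear scale, 1 per probe set, made by the authors with MAS5 and GCOS, with no versions stated. They had been scaled by the authors so that every array had the same trimmed mean signal, 99.98. Detection calls were not used here. The table held 54675 probe sets, 62 of them controls. A symbol was taken from the probe and gene table of the platform: 41091 probe sets had 1 symbol, 1801 had several and 11721 had none, the latter kinds being left out of the gene tests, which left 19777 genes. Of these 19735 were matched to RefSeq records and 4 symbols were updated. No pair among the 78 pairs of arrays held identical values, and their Spearman correlations ran from 0.82 to 0.91.

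Signals were set to a floor of 3.53, the 20th percentile of all values, and put on the log2 scale with no further normalization. Probe sets with a mean above the 40th percentile (log2 3.34) were kept, 32768 in all, and for each gene the probe set with the highest mean was used, giving 13764 genes, with 1.33% of their values at the floor. Linear models were fitted with limma 3.58.1 in R 4.3.3 to all 13 arrays at once, with moderated statistics and a mean-variance trend (9 residual degrees of freedom, 13.1 with the moderation). Genes passed at a Benjamini-Hochberg adjusted p under 0.05, two-sided, within each comparison. The comparisons were CCND1 with GFP siRNA, CDK4 with GFP siRNA, CCND1 with CDK4 siRNA, GFP siRNA with untreated cells, and the mean of both knockdowns with GFP siRNA. The comparisons of each knockdown with untreated cells were added after the data were examined.

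Before the data were examined 24 gene lists were fixed, covering the cell cycle, neuronal and sympathoadrenal differentiation, stress and metabolic responses, markers of other cell types and RNA quality. Each was tested with camera at a preset correlation of 0.01, adjusted over the 24 lists, and again with the correlation estimated from the data and with fry, which tests whether a list's genes move one way on balance. The count of members past the test was also taken when adjusted over the list alone.

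The rule for the genes named, also fixed before the data were examined, took CCND1 and CDK4, and the 8 largest rises and 8 largest falls (5 and 5 between CCND1 and CDK4 siRNA) among called genes whose groups did not overlap and whose higher group had a mean above log2 3.96, the median of all probe sets. It added the 4 members with the smallest p of the DNA replication and neuronal differentiation lists, the 2 with the smallest p of each other list past camera, and the called members of other lists with 3 or fewer of them. Other members named are said to have been chosen after their values were seen. Of 187 named and called pairs of gene and comparison, the genes had 160 other probe sets, of which 41 were called the same way by limma, 72 had less than 0.5 of the size or the opposite sign (15 had the opposite sign) and 0 were called the opposite way. Of 106 such pairs with another probe set, 67 had none called the same way, so sizes of single genes rest on the brightest probe set.

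The labels do not say whether equal replicate numbers mark paired samples, so deviations from group means were correlated between arrays. Arrays of equal number correlated at 0.54, 0.28 and 0.30 for CCND1 with GFP siRNA and at 0.48, 0.30 and 0.25 for CDK4 with GFP siRNA. For GFP siRNA with untreated cells, number 2 correlated at −0.23. Of the 13 arrays, 9 correlated best with an array of their own number. The first component of the deviations, 43.2% of their variance, divided the arrays into a set of 5 and a set of 8. Arrays of different groups correlated at 0.15 to 0.59 within a set and at −0.47 to −0.20 between sets. The equal-numbered pairs of CCND1 or CDK4 with GFP siRNA above all lay within a set and inside its range. Their values therefore cannot tell pairing by number from the array set, and the replicate block stands beside the results as an alternative. A block for the array set left 8 residual degrees of freedom and the replicate block 6. Since the sets were found in the deviations that the fit uses, the counts with the array-set block can be too high.

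Alternatives fixed before the data were examined were quantile normalization, median centring, no floor, an offset of 32 in place of the floor, no filter, a filter at the 60th percentile, the mean of all probe sets of a gene, a fixed or random replicate block, the compared groups alone, no trend, array weights, a 2-fold threshold, all probe sets as the unit, and leaving out each array in turn. The array-set block and the set of 8 arrays alone were added after the data were examined. Labels exchanged within replicate numbers were also added then, as were the splits of the GFP arrays between comparisons and the sizes on other probe sets. All 144 such labellings were first fitted, and a random draw from them missed the 3 that keep the GFP arrays together, so these were included on purpose in the 100 used. A test of the array sets by the count of genes that set the GFP arrays apart was dropped because the block raised the counts of every group, and a 2nd, on the sizes of their differences with the set as a term, because the choice of genes nearly fixed its outcome. The 3rd and last chose genes in the set of 8 alone and followed them in the other 5 arrays, with its bounds set before it was run. Where leaving out an array left 2 in a group, limma pooled the spread over the groups.

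The procedure was tested on simulated data with 200 genes changed. Over 25 draws 72.1%, 71.6%, 69.7% and 72.0% of log2 changes of 2 were recovered for CCND1 with GFP, CDK4 with GFP, CCND1 with CDK4 and GFP with untreated, and 19.0%, 18.3%, 14.8% and 18.6% of log2 changes of 1. At 0.5 the shares were 1.3%, 1.5%, 0.7% and 1.5%. A single draw was tried first and exceeded the limit set for false calls between CCND1 and CDK4 siRNA (10.3% of 68 calls in the first of the 25 draws), so the share over all 25 draws was taken instead, with a limit of 6% chosen in that same revision, and it was 5.07%, 5.62%, 5.68% and 5.01%. The highest in a single draw was 12.3%. The simulated noise was independent between genes and held no array sets, and few genes were changed. These shares of recovered and false calls therefore need not hold for the real arrays.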

Results

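Transcript levels were measured in IMR-32 cells, an established human neuroblastoma cell line, on 13 whole-genome expression arrays. Untreated cells collected at 0 h gave 3 arrays. Cells collected 48 h after transfection gave 4 arrays with a control siRNA against GFP, 3 with an siRNA against CCND1 (cyclin D1) and 3 with an siRNA against CDK4. The series text calls the experiments biological triplicates, although the GFP group holds 4 arrays, and the sample labels do not say whether the replicates were separate cultures, so the p-values measure the spread between these arrays. Every array had a trimmed mean signal of 99.98, and the median signal ran from 15.9 to 22.5. Detection calls were not used here, and the number of arrays limits the precision.

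The arrays also fell into 2 sets that cut across the groups, seen after the data were examined. In 5 arrays (untreated replicate 1, GFP siRNA replicates 1 and 2, CCND1 siRNA replicate 1 and CDK4 siRNA replicate 2) the 3′ to 5′ signal ratio of the actin control probe sets was 1.30 to 2.11. In the other 8 arrays it was 2.84 to 3.70. Cytosolic ribosomal protein genes were 0.55 higher on the log2 scale in the set of 8 (50 of 52 genes past the test; camera adjusted p = 8.66e-12, and adjusted p = 0.513 with an estimated correlation). Mitochondrial oxidative phosphorylation genes were 0.57 higher there, with 44 of 52 higher and 4 lower (adjusted p = 4.74e-10, and adjusted p = 0.513 with an estimated correlation). MYCN and MYC targets were 0.33 higher, with 22 of 34 higher and 5 lower (adjusted p = 0.041, and adjusted p = 0.513 with an estimated correlation). The sets were found in the deviations of these same arrays, which raises such differences. Each group had arrays in both sets.

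**Figure D1:**
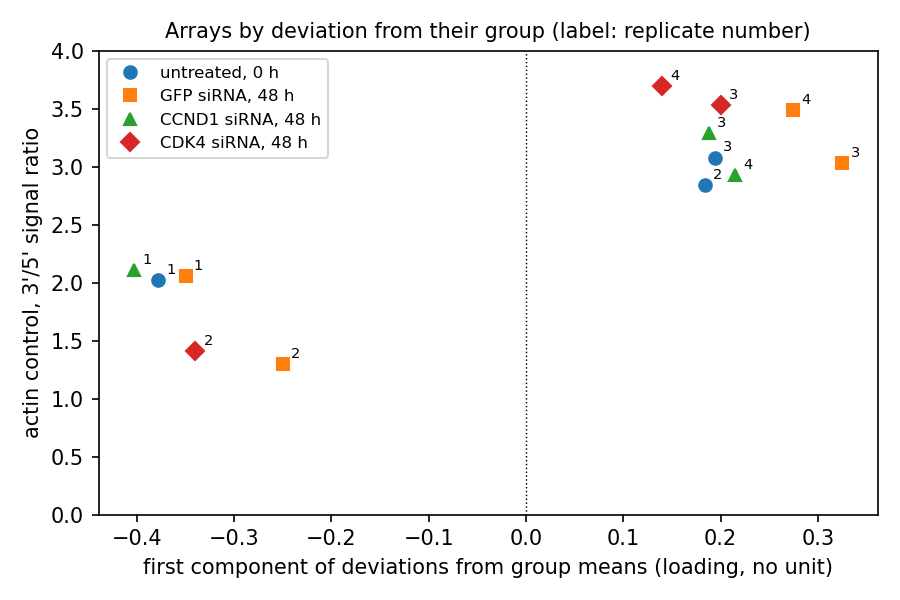
Actin 3′ to 5′ signal ratio (y axis) of each of the 13 arrays against its loading on the first component of deviations from group means (x axis, no unit, 43.2% of their variance), coloured by group. The 5 arrays of one set lie at 1.30 to 2.11 and the 8 of the other at 2.84 to 3.70.

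The first question was how far each siRNA lowered its own target. CCND1 (chromosome 11), on the brighter of its probe sets, had a mean signal of 1450 ± 165 (SD, n = 4) with GFP siRNA and 527 ± 27.6 (SD, n = 3) with CCND1 siRNA. This was a log2 fold change of −1.46 (SE 0.14, limma adjusted p = 4.31e-05), with 36.4% of the control signal left. A second CCND1 probe set also fell, by 1.60 on the log2 scale (adjusted p = 0.0324 over all probe sets). CDK4 (chromosome 12) had a mean signal of 2820 ± 536 (SD, n = 4) with GFP siRNA and 407 ± 187 (SD, n = 3) with CDK4 siRNA. Its log2 fold change was −2.89 (SE 0.33, adjusted p = 7.01e-05), leaving 13.5% of the control signal.

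Each siRNA also came with a change in the other transcript. CDK4 fell to 1080 ± 338 (SD, n = 3) with CCND1 siRNA, 37.2% of the control signal (limma adjusted p = 0.013). CCND1 rose to 2120 ± 243 (SD, n = 3) with CDK4 siRNA, a log2 fold change of 0.54 (adjusted p = 0.013), while the second CCND1 probe set did not pass (0.78, adjusted p = 0.306 over all probe sets). In untreated cells CCND1 had a mean signal of 1000 ± 14.7 and CDK4 one of 3090 ± 749 (SD, n = 3 each). From untreated cells to GFP siRNA, CCND1 rose by 0.53 on the log2 scale (adjusted p = 0.0434, a call lost on leaving out any of 6 of the 7 arrays). The second probe set did not pass there (0.13, adjusted p = 0.983 over all probe sets), and CDK4 changed by −0.12, which did not pass the test (adjusted p = 0.916).

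**Figure D2:**
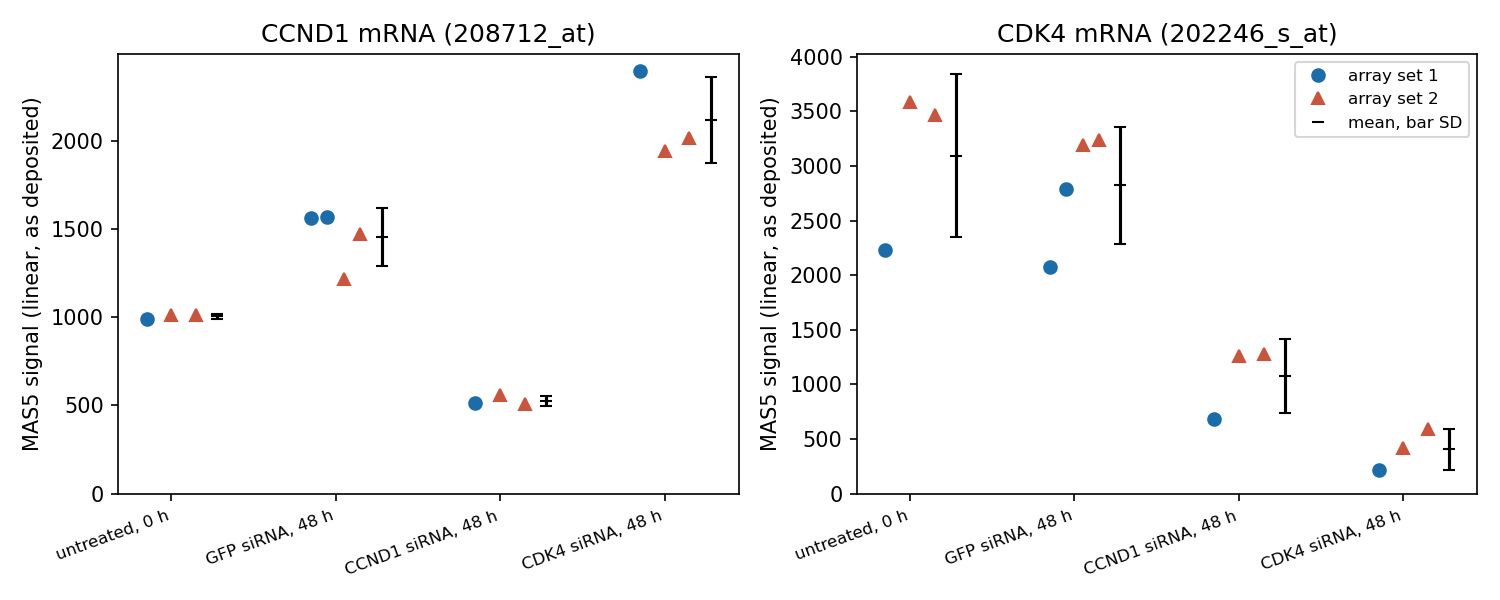
Signal of the CCND1 and CDK4 probe sets (linear intensity) on each array, by group, with the group mean and SD (circles, the array set of 5; triangles, the set of 8). CCND1 had its lowest group mean, 527, with CCND1 siRNA, and CDK4 its lowest, 407, with CDK4 siRNA.

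The comparison of CCND1 siRNA with GFP siRNA asked which transcripts changed when cyclin D1, the regulatory partner of CDK4 in the G1 phase, was lowered. Cell cycle genes fell. Of 54 measured DNA replication and G1/S genes 24 fell and none rose, with a median log2 fold change of −0.72. The 4 members with the smallest p were CDC6 (−1.85, SE 0.21) and DTL (−1.67, SE 0.22), which act in the licensing of replication origins and its control, the helicase subunit MCM7 (−1.55, SE 0.23) and the polymerase epsilon subunit POLE2 (−0.90, SE 0.16), with 3 CCND1 and 4 GFP arrays in each. Of 59 G2/M and mitosis genes 31 fell and none rose (median −1.07), among them the spindle factor TPX2 (−1.30, SE 0.18) and the kinesin KIF2C (−1.20, SE 0.17).

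These falls passed the set test with its preset correlation (camera adjusted p = 3.47e-17 for DNA replication and 1.81e-23 for G2/M) but not with an estimated one (adjusted p = 0.056 with an estimated correlation for each). When adjusted over the list alone, 35 DNA replication genes fell and 1 rose, and 45 G2/M genes fell. The replicate block gave 42 DNA replication genes that fell and 1 that rose, and 52 G2/M genes that fell. The D-type cyclin, CDK and RB pathway list had 4 of 27 members lower, CCND1 itself, CCND3 (−1.40), E2F7 (−1.29) and CDK4, and none higher (median −0.30, camera adjusted p = 0.00576, adjusted p = 0.056 with an estimated correlation). The replicate block gave 10 lower and 3 higher. E2F7 was named after its values were seen.

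Signals of replication-dependent histone genes moved the opposite way to the other cell cycle genes with CCND1 siRNA. Only 10 of the 24 listed genes were measured, and which forms of these transcripts the arrays report was not tested. Of the 10 measured, 7 rose and none fell (median 1.52), with H2BC21 at 2.58 (SE 0.19, adjusted p = 1.2e-05) and H4C8 at 2.60 (SE 0.31). Their set test gave a camera adjusted p of 5.93e-07 (adjusted p = 0.056 with an estimated correlation). Cholesterol synthesis genes had 8 of 26 members higher and none lower (median 0.43, camera adjusted p = 0.000707, adjusted p = 0.125 with an estimated correlation). Their members TM7SF2, a sterol reductase, and STARD4, a sterol carrier, rose by 3.07 (SE 0.45) and 2.57 (SE 0.30). In the fit with the replicate block 8 histone genes rose, and 13 cholesterol synthesis genes rose and 2 fell.

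Genes of the neuronal differentiation list went both ways with CCND1 siRNA. Of 37 measured, 5 rose and 5 fell (8 and 5 when adjusted over the list alone, 11 and 5 with the replicate block), and the median of 0.13 became −0.03 after median centring of the arrays. The list did not pass the set test (camera adjusted p = 0.797, adjusted p = 0.95 with an estimated correlation). DPYSL3, a growth cone protein, fell by 1.80 (SE 0.27), the neurofilament NEFM fell by 0.86 (SE 0.16), the secreted neuropeptide precursor VGF fell by 1.24 (SE 0.26), and the ubiquitin hydrolase UCHL1 rose by 1.29 (SE 0.26), though not on its other probe set (−0.27).

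Among smaller groups, 7 of 37 unfolded protein and ATF4 stress response genes fell and 1 rose with CCND1 siRNA (median −0.17, camera adjusted p = 0.0203, adjusted p = 0.056 with an estimated correlation, and adjusted p = 0.0509 with the filter at the 60th percentile). Between CCND1 siRNA and untreated cells 3 rose and 1 fell, and the list did not pass (median 0.07, camera adjusted p = 0.983). With GFP siRNA its median was 0.35 above untreated cells. The serine synthesis enzyme PSAT1 fell by 1.59 (SE 0.14) and the amino acid transporter SLC7A1 fell by 1.20 (SE 0.16). Of 28 immediate early genes 7 fell and 1 rose (median −0.19, camera adjusted p = 0.0356, adjusted p = 0.125 with an estimated correlation), with KLF2 at −2.92 (SE 0.34) and EGR1 at −2.25 (SE 0.36), both transcription factors. The immediate early call was lost without GFP siRNA replicate 1 (adjusted p = 0.0603), with the array-set block (0.0604), in the set of 8 alone (0.191), after quantile normalization (0.053) and with the filter at the 60th percentile (0.13). Against untreated cells 3 immediate early genes rose with CCND1 siRNA and none fell (median 0.31, camera adjusted p = 0.24). With GFP siRNA the median of that list was 0.53 above untreated cells. Of 52 ribosomal protein genes 1 rose, RPL11 (0.87, adjusted p = 0.0193), and RPL8 stood at 1.08 without passing the test (adjusted p = 0.0567). That list had a median of 0.29 and a camera adjusted p of 0.000707 (adjusted p = 0.797 with an estimated correlation), and it is the list that differed by 0.55 between the array sets. Its median was 0.02 after quantile normalization (adjusted p = 0.206), and fry gave adjusted p = 0.327. With the replicate block 14 stress response genes fell and 5 rose, 9 immediate early genes fell and 2 rose, and 7 ribosomal protein genes rose.

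The remaining lists did not pass camera at its preset correlation in this comparison. Fry, which compares no list with other genes, passed p53 targets (adjusted p = 0.000153), heat shock (0.00876), synapse (0.017), neurotrophin and receptor (0.017), hypoxia (0.025) and neural progenitor genes (0.0357). With the replicate block camera passed MYCN and MYC targets (adjusted p = 0.035) and heat shock genes (0.0397), and with the array-set block the first of these (0.0163) but not the other (0.056). The synapse list had 6 members higher and 2 lower, the sympathoadrenal list 3 and 3, the neural progenitor list 3 and 2, the p53 target list 4 and 2, hypoxia and glycolysis 7 and 2, and oxidative phosphorylation 3 and 1. Of the MYCN and MYC targets, lactate dehydrogenase LDHA rose (1.05) and ornithine decarboxylase ODC1 fell (−0.95). In the neurotrophin and receptor list ALK (−1.56), KITLG (−0.96) and IGF1R (−0.77) fell, and in the heat shock list HSPA4L (−1.54), STIP1 (−1.20) and HSPH1 (−0.80) fell. The death receptor FAS rose (1.77) as the 1 change in the apoptosis list, and the interferon-response genes ISG15 (2.73) and CMPK2 (0.98) rose. FAS did not pass on its other probe set (0.55). Of the fibroblast and substrate-adherent cell markers COL6A1 rose (1.96) and LUM (−2.83) and VIM (−0.96) fell. No Schwann and glial, blood and endothelial, or RNA quality and housekeeping gene passed, and with the replicate block 1 housekeeping gene was lower. The block also gave more members in most other lists, such as 8 higher and 7 lower in the sympathoadrenal list, 9 and 3 among p53 targets and 2 and 8 among MYCN and MYC targets.

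The largest changes whose groups did not overlap lay outside the cell cycle lists. LDB3, a muscle Z-disc protein, rose by 4.58 (SE 0.81), TNFRSF4 by 4.45 (SE 0.66, with 3 of the 4 GFP arrays at the floor), PTPRN2, a protein of secretory granules, by 4.08 (SE 0.42, with 2 of the 4 at the floor), and TP53INP1 by 3.79 (SE 0.28). ABCA12, CFAP95, SCUBE1 and MFSD6 rose by 3.72, 3.70, 3.67 and 3.44. LDB3 and ABCA12 each had 1 GFP array at the floor, and TRIM7, among the falls, had 2 of the 3 CCND1 arrays there. The sizes of these changes thus depend on where the floor was set. Of the rises MFSD6 had the smallest adjusted p, 1.04e-06. TRIM7 (−3.27), the integrin subunit ITGB8 (−3.12), the guidance cue SEMA3C (−2.88), dystrophin DMD (−2.83, SE 0.25), HS3ST3A1 (−2.52) and STEAP1B (−2.45) fell, together with KLF2 and LUM above. From untreated cells to GFP siRNA, ITGB8 had risen by 3.86 and LUM by 2.73. On another probe set of the same gene TNFRSF4 (−0.14), TRIM7 (−0.07), ITGB8 (−0.06), DMD (−0.02), SEMA3C (−0.36), KLF2 (−0.38), SCUBE1 (0.78) and LUM (−0.92) did not pass. The GFP arrays stood apart from all 3 other groups for LDB3, SCUBE1, MFSD6, DMD, DPYSL3, VGF, TM7SF2, SLC7A1 and EGR1. Of these only MFSD6 (2.37), SCUBE1 (1.66) and DMD (−1.19) also passed between CCND1 siRNA and untreated cells.

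In all, limma called 1582 of 13764 genes between CCND1 and GFP siRNA, 866 higher and 716 lower, and 888 of them at least 2-fold. Median centring moved the median of all genes from 0.07 to −0.09 and the share of called genes that were higher from 54.7% to 38.0%. With replicate number as a block 3637 genes passed, with the array set as a block 4261, and 3609 in the set of 8 alone. Without CCND1 siRNA replicate 3 the count was 894, and without replicate 4 it was 893. Of 50 genes named for this comparison as called, 10 lost the call when some 1 array was left out (CMPK2, HSPH1, STEAP1B, FAS, IGF1R, ISG15, RPL11, COL6A1, CFAP95 and STIP1).

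The comparison of CDK4 siRNA with GFP siRNA asked the same of the kinase itself. Cell cycle genes fell in larger numbers. Of 54 DNA replication and G1/S genes 45 fell and none rose (median −1.34), among them DTL (−2.35, SE 0.22), CDC6 (−2.19, SE 0.21), the ribonucleotide reductase subunit RRM2 (−1.88, SE 0.19) and the helicase subunit MCM6 (−1.72, SE 0.16), with 3 CDK4 and 4 GFP arrays in each. Of 59 G2/M and mitosis genes 54 fell and none rose (median −2.05), with TPX2 at −2.31 (SE 0.18) and the mitotic kinase AURKA at −2.18 (SE 0.17). When adjusted over the list alone, 50 and 57 fell, and with the replicate block 51 and 59.

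Camera gave adjusted p = 3.34e-31 for the DNA replication list and 3.66e-42 for the G2/M list with CDK4 siRNA (adjusted p = 0.0144 with an estimated correlation for each). The D-type cyclin, CDK and RB pathway list had 9 of 27 members lower, the targeted CDK4 among them, and 1 higher, CCND1. The list, tested with its siRNA target included, had a median of −0.60 (camera adjusted p = 0.000427, and 0.0144 with an estimated correlation). Its member with the smallest p was the repressor E2F7 (−2.61, SE 0.25), which did not pass on its other probe set (−0.19). Its counts were 13 lower and 3 higher with the replicate block. The histone genes rose again, 7 of 10 with none lower (median 2.17), H2BC21 by 3.67 (SE 0.19, adjusted p = 4.49e-07) and H4C8 by 3.49 (SE 0.31). Their camera adjusted p was 2.99e-07 (adjusted p = 0.0615 with an estimated correlation).

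Neuronal differentiation genes again went both ways with CDK4 siRNA, 6 of 37 higher and 5 lower (12 and 5 when adjusted over the list alone, 11 and 8 with the replicate block). Their median was 0.02, below 0 after either scaling alternative, and the set test was not passed (camera adjusted p = 0.826). The intermediate filament INA fell by 1.31 (SE 0.20) and DPYSL3 fell by 1.38 (SE 0.27), while the growth-associated protein GAP43 rose by 0.88 (SE 0.17) and UCHL1 by 1.19 (SE 0.26), the latter not on its other probe set (−0.28). DPYSL3 was high in the GFP arrays alone, with a mean log2 signal of 8.72 against 7.34 with CDK4 siRNA and 7.39 in untreated cells. GAP43 was also the 1 gene of the Schwann and glial list that passed. Of the stress response list 6 of 37 members fell and none rose, among them 2 subunits of an amino acid transporter, SLC7A11 by 2.18 (SE 0.24) and SLC3A2 by 1.26 (SE 0.22) (list median −0.27, adjusted p = 0.0318, and adjusted p = 0.0615 with an estimated correlation). That call was lost without GFP siRNA replicate 2 (adjusted p = 0.0515), without CDK4 siRNA replicate 3 (0.116), with the random replicate block (0.0625) and with the filter at the 60th percentile (0.0683). Between CDK4 siRNA and untreated cells 2 members rose and 3 fell, and the list did not pass (median 0.09, camera adjusted p = 0.993).

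Of the ribosomal protein genes 3 of 52 rose with CDK4 siRNA, RPL11 (0.88) and RPL8 (1.16) among them (median 0.27, camera adjusted p = 0.00265, adjusted p = 0.923 with an estimated correlation), in the list that differed by 0.55 between the array sets. The call was lost without GFP siRNA replicate 2 (adjusted p = 0.136), without CDK4 siRNA replicate 3 (adjusted p = 0.193, with medians of 0.11 and 0.12), after quantile normalization (median 0.04) and with fry (adjusted p = 0.42). No other list passed camera at its preset correlation without a block. The sympathoadrenal list (adjusted p = 0.0935) passed with the replicate block (0.037), with the array-set block (0.0113) and with fry (0.0166), but not with an estimated correlation (0.569). Oxidative phosphorylation (0.0566) passed with the array-set block (0.018). The synapse list had 6 members higher and 4 lower, the sympathoadrenal list 6 and 2, the neurotrophin list 1 and 3, the p53 target list 4 and 3, cholesterol synthesis 3 and 1, hypoxia and glycolysis 6 and 2, immediate early genes 2 and 4, oxidative phosphorylation 3 and 1 and the fibroblast markers 3 and 5. In the neural progenitor list HES6 (2.54) and DLL3 (1.07) rose and VANGL2 fell (−1.12). Of the MYCN and MYC targets NOLC1 rose (0.71) and POLR1B (−0.99) and ODC1 (−0.60) fell. On other probe sets NOLC1 (0.08 and 0.21) and POLR1B (−0.25, −0.29 and −0.4) did not pass. In the apoptosis list BCL2, which opposes cell death, rose (1.33), DIABLO rose (0.56) and the apoptosome scaffold APAF1 fell (−3.16). Neither BCL2 (0.15 and 0.86) nor APAF1 (−1.31) passed on other probe sets. IFIT2 rose (1.87) in the interferon list, and HSPA4L rose (0.90) and HSPB8 fell (−1.05) in the heat shock list. IFIT2 (0.5), HSPA4L (0.06) and HSPB8 (0.26) did not pass on another probe set. No blood and endothelial or housekeeping gene passed, and with the replicate block 3 housekeeping genes were lower. That block gave more members in most lists, such as 11 stress response genes lower and 3 higher, 8 ribosomal protein genes higher, and 14 sympathoadrenal genes higher and 4 lower.

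The largest non-overlapping rises with CDK4 siRNA were EPAS1, a hypoxia-inducible transcription factor (4.23, SE 0.50), ATL3 (4.20), H2AC8 (4.11), ACTL8 (3.99), CFAP95 (3.88), ABCA12 (3.82) and H2BC4 (3.82, with 3 of the 4 GFP arrays at the floor). SH3BGR was at least 17.5-fold higher, since all 4 GFP arrays were at the floor. ATL3, ACTL8, ABCA12 and IFIT2 each had 1 GFP array there, and MFAP4, AEBP1 and APAF1 each 1 CDK4 array, so the sizes of these changes depend on where the floor was set. The largest falls were RNF112 (−3.56), the CDK-activating phosphatase CDC25A (−3.37), MFAP4 (−3.29), ZNF367 (−3.27, SE 0.25), AEBP1 (−3.25), the kinetochore motor CENPE (−3.24), ETV4 (−3.21) and CDCA8 (−3.18), a member of the chromosomal passenger complex. On another probe set EPAS1 did not pass (0.53) and ATL3 rose by 1.11. The GFP arrays stood apart for ATL3 and HES6, which did not pass between CDK4 siRNA and untreated cells (1.48 and 0.53).

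Between CDK4 and GFP siRNA limma called 2509 of 13764 genes, 1201 higher and 1308 lower, and 1505 at least 2-fold. Median centring moved the median of all genes from 0.07 to −0.04 and left 884 higher and 1321 lower. With replicate number as a block 4462 genes passed, with the array set as a block 5103, and 4208 in the set of 8 alone. Of 47 genes named as called, 9 lost the call when some 1 array was left out (HSPA4L, DIABLO, IFIT2, RPL8, HSPB8, MFAP4, RPL11, CCND1 and DLL3).

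**Figure D3:**
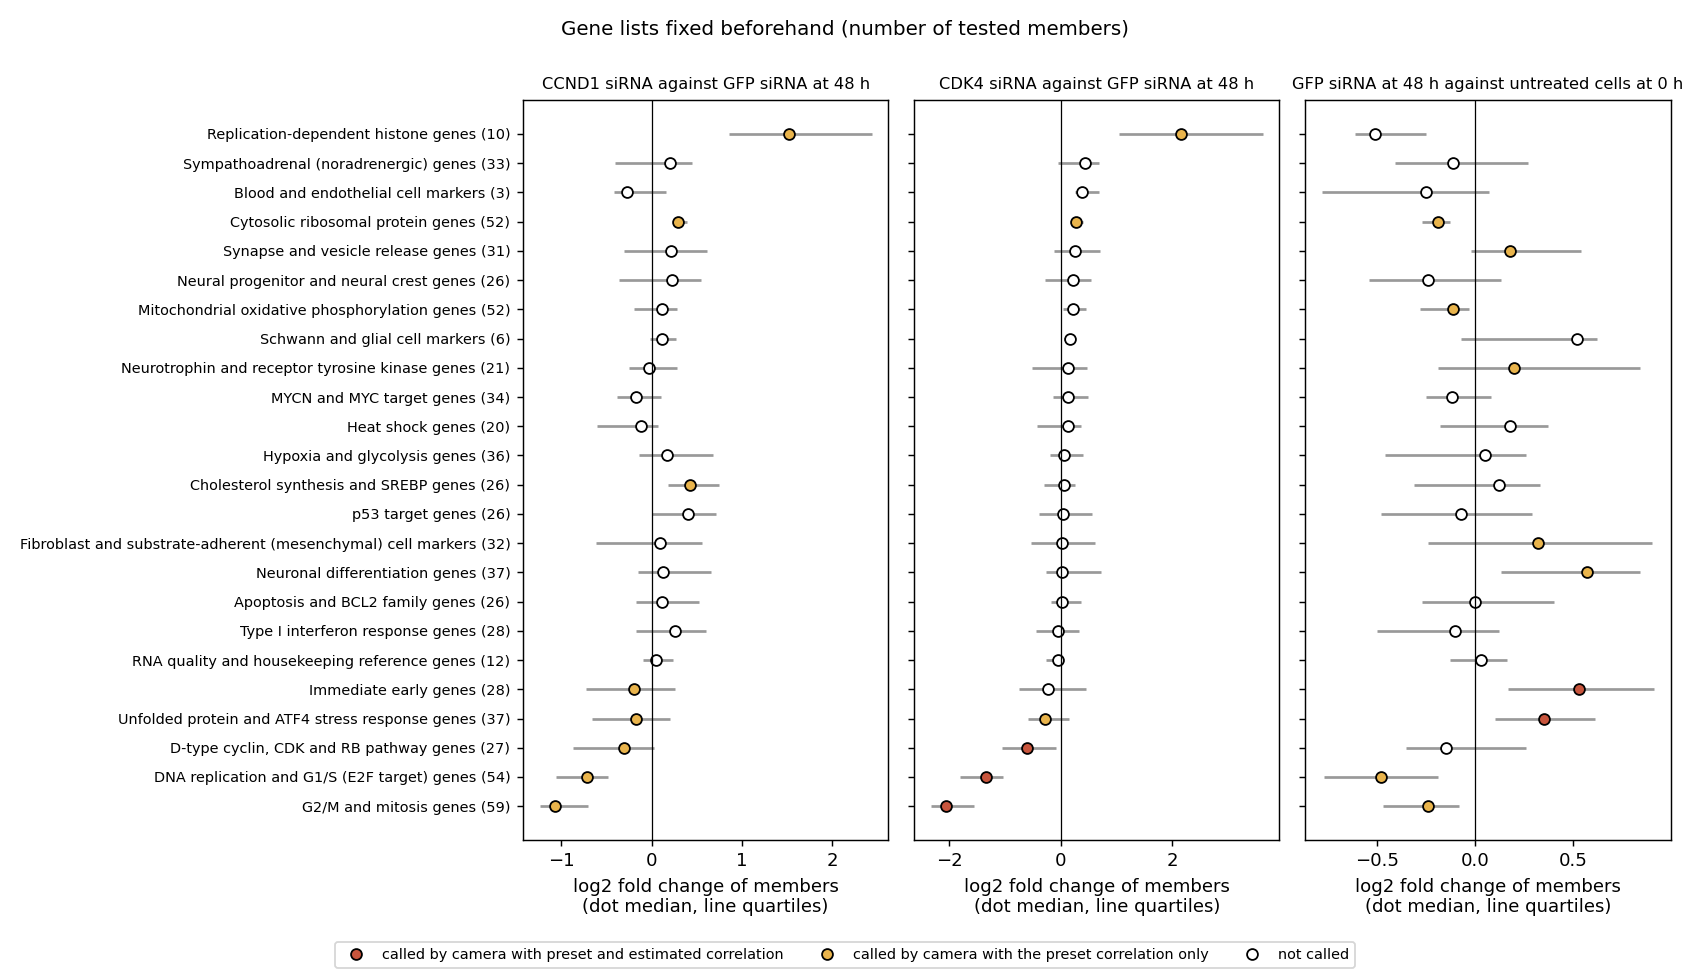
Median log2 fold change of each fixed gene list, with the quartiles of its members, in 3 comparisons (CCND1 siRNA against GFP siRNA, CDK4 siRNA against GFP siRNA, and GFP siRNA against untreated cells), each panel with its own range on the x axis (filled dots, lists past camera, the darker ones also with an estimated correlation). The G2/M list had medians of −1.07, −2.05 and −0.24, and the histone list 1.52, 2.17 and −0.51.

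The direct comparison of CCND1 with CDK4 siRNA tested whether the knockdowns differed. They were of unequal depth, with 36.4% of the CCND1 signal and 13.5% of the CDK4 signal left, and each used 1 siRNA. With CCND1 siRNA the CDK4 signal was also at 37.2% of the control, so both transcripts were lower in those arrays. A difference can thus come from the depth, the siRNAs or the genes lowered, which this comparison does not separate. Cell cycle genes were higher with CCND1 siRNA. Of 54 DNA replication genes 15 were higher and none lower (median 0.68, 30 when adjusted over the list alone), including GINS1 (1.42, SE 0.26), the S-phase cyclin CCNE2 (1.21, SE 0.23), MCM6 (1.01, SE 0.17) and RRM2 (1.01, SE 0.20), with 3 arrays per group. Of 59 G2/M genes 31 were higher and none lower (median 1.01), including CCNB2 (1.39, SE 0.19) and SPC25 (1.54, SE 0.22). The counts were 31 and 51 with the replicate block. Camera adjusted p was 5.98e-13 and 9.76e-22 (adjusted p = 0.147 with an estimated correlation for each). CCND1 was lower by −2.00 (SE 0.14, adjusted p = 1.45e-05) and CDK4 higher by 1.47 (SE 0.35, adjusted p = 0.0196).

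Cholesterol synthesis genes were also higher with CCND1 than with CDK4 siRNA, 7 of 26 with none lower (median 0.47, camera adjusted p = 0.000746, adjusted p = 0.194 with an estimated correlation), with IDI1 at 1.12 (SE 0.17) and ACAT2 at 0.78 (SE 0.14). Histone genes had 1 member higher, the linker histone H1-2 (1.20), and 2 lower, H2BC21 (−1.09) and H2AC8, of 10 (median −0.73, adjusted p = 0.0164, and adjusted p = 0.362 with an estimated correlation). The sympathoadrenal list had 1 of 33 members higher, PNMT (2.69, SE 0.52), which makes adrenaline, and 2 lower, among them GCH1 (−1.09, SE 0.14), which makes the tetrahydrobiopterin cofactor (median −0.29, adjusted p = 0.04, and adjusted p = 0.335 with an estimated correlation). The MYCN and MYC targets RRP9 (−1.42) and NME1 (−0.57) were lower (list median −0.29, adjusted p = 0.012, and adjusted p = 0.631 with an estimated correlation), in a list that differed by 0.33 between the array sets. Without CCND1 siRNA replicate 1 the histone, sympathoadrenal and MYC target calls were lost (adjusted p = 0.0808, 0.13 and 0.13) and their medians shrank to −0.39, −0.18 and −0.11, and the sympathoadrenal call also without CDK4 siRNA replicate 3 (0.0613), CCND1 siRNA replicate 4 (0.0561) or CDK4 siRNA replicate 4 (0.0527), after quantile normalization (0.0766), with array weights (0.0508), without the trend (0.0564) and with no filter (0.056). The histone call was lost with no filter (0.0652), and fry passed none of these 3 lists (0.0736, 0.0845 and 0.219).

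In the heat shock list HSPB8 was higher (1.16) and HSPA4L lower (−2.44) with CCND1 siRNA (median −0.24, camera adjusted p = 0.04, adjusted p = 0.169 with an estimated correlation). That call was lost on leaving out CCND1 siRNA replicate 3 or 4 or CDK4 siRNA replicate 2 or 3 (adjusted p = 0.0866, 0.0628, 0.0774 and 0.0613), without the trend (0.0564) and with the mean of all probe sets (0.078). In the oxidative phosphorylation list SDHD was higher (1.85) and NDUFA10 lower (−1.41), the latter not past the test on other probe sets (−0.05, −0.65 and −0.34). That list had a median of −0.17 and an adjusted p of 0.04 (adjusted p = 0.0677 with the replicate block, 0.0935 with a random one, 0.0766 after quantile normalization, 0.6 with fry and 0.923 with an estimated correlation), and it is the list that differed by 0.57 between the array sets. Its median was 0.01 without CCND1 siRNA replicate 1, and its call was also lost without CDK4 siRNA replicate 3 or 4 (adjusted p = 0.177 and 0.15). Neuronal differentiation genes had 3 of 37 members higher, NCAM1 (1.33), MAP1B (0.91) and SCG2 (0.85), and 2 lower, GAP43 (−1.01) and NEFM (−0.62, named after its values were seen). Their set test was not passed (median 0.02, −0.04 after median centring, camera adjusted p = 0.95).

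The other lists did not pass camera at its preset correlation between CCND1 and CDK4 siRNA. Fry passed p53 targets (adjusted p = 0.00113) and the RB pathway list (0.013), the latter also with the array-set block in camera (0.0497). The RB pathway list had 5 members higher and 2 lower, the synapse list 3 and 1, the neurotrophin list 3 and 4, the p53 target list 5 and 1 and the fibroblast markers 3 and 4. SOX9 (−2.50) was lower in the neural progenitor list. APAF1 (2.12) was higher and BCL2 (−1.66) lower in the apoptosis list. Neither APAF1 (0.12) nor BCL2 (−0.49 and −0.36) passed on other probe sets. IRF1 (1.74) was higher in the interferon list, CHAC1 (1.69) and SEL1L (0.71) were higher and PSAT1 (−1.52) lower in the stress response list. In the hypoxia list SLC2A1 (0.80) and P4HA2 (0.84) were higher and PKM (−0.79) lower, and in the immediate early list FOSL2 (1.91) was higher and KLF2 (−2.14) and SRF (−1.11) lower. None of these hypoxia and immediate early genes passed on another probe set, with FOSL2 at −0.3, 0.41 and 0.57 and SRF at 0.05. TFRC (0.71) was the 1 housekeeping gene that passed, GAP43 the 1 Schwann and glial gene, and no ribosomal protein or blood and endothelial gene passed.

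The largest non-overlapping differences were higher RNF112 (3.83), AEBP1 (3.65), SOWAHA (3.63), CABP7 (3.40) and MFAP4 (3.28), and lower EPAS1 (−4.43), ACTL8 (−4.31), FCRLB (−3.29), SAXO5 (−3.10) and LUM (−3.09) with CCND1 siRNA. Of the CDK4 arrays 2 were at the floor for CABP7 and 1 each for AEBP1, MFAP4 and APAF1, and of the CCND1 arrays 2 for FCRLB and 1 for SAXO5, so these sizes depend on the floor. On its other probe set EPAS1 did not pass (−1.29), nor did LUM (−1.62). Limma called 1298 of 13764 genes, 808 higher and 490 lower, and 781 at least 2-fold. After median centring 527 were higher and 426 lower, and the share higher went from 62.2% to 55.3%. With the replicate block 3002 genes passed, with the array-set block 3924, and 3392 in the set of 8 alone. Leaving out 1 array gave 718 (CCND1 siRNA replicate 3), 789 (CCND1 replicate 4), 864 (CDK4 siRNA replicate 2), 726 (CDK4 replicate 3) and 830 (CDK4 replicate 4). Of 48 genes named as called, 17 lost the call when some 1 array was left out (SAXO5, SRF, TFRC, IRF1, MFAP4, NCAM1, NME1, P4HA2, SOX9, APAF1, CHAC1, SEL1L, CDK4, H1-2, HSPB8, FCRLB and RRP9).

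The comparison of GFP siRNA at 48 h with untreated cells at 0 h held transfection, time in culture and traits of the GFP arrays. Transfection and time are not separated by the design. In 66 higher and 154 lower genes the GFP arrays also stood apart from both knockdowns, which were transfected and collected at 48 h too. Those changes were thus not shared by all transfected cells at 48 h. Neuronal differentiation genes rose. Of 37 measured 10 rose and none fell (median 0.57; 16 rose and 1 fell when adjusted over the list alone), among them the microtubule-regulating proteins DCX (2.67, SE 0.26) and STMN4 (2.78, SE 0.28), the membrane scaffold ANK2 (1.32, SE 0.16) and the axonal motor KIF5C (1.15, SE 0.14), over 4 GFP and 3 untreated arrays. Camera gave adjusted p = 7.23e-11 (adjusted p = 0.0713 with an estimated correlation). DNA replication genes had 6 of 54 members lower and none higher (median −0.48; 20 lower when adjusted over the list alone), with CCNE2 at −2.18 (SE 0.22), E2F2 at −1.48, thymidylate synthase TYMS at −1.16 and POLA2 at −0.95 (adjusted p = 6.01e-11, and adjusted p = 0.101 with an estimated correlation).

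No single G2/M gene passed between GFP siRNA and untreated cells without a block (13 fell with the replicate block), with SPC25 at −0.75 (adjusted p = 0.0616) and CENPA at −0.92 (adjusted p = 0.0906), and the list had a median of −0.24 (camera adjusted p = 0.00121, adjusted p = 0.117 without untreated replicate 1, adjusted p = 0.222 with fry, and adjusted p = 0.608 with an estimated correlation). Immediate early genes rose, 6 of 28 with 1 lower (median 0.53), including the ERK phosphatase DUSP6 (2.86, SE 0.32) and EGR1 (2.46, SE 0.36), with adjusted p = 8.15e-06 (0.0171 with an estimated correlation). Of the stress response list CHAC1 (2.25) and SLC7A1 (0.61) rose and none fell (median 0.35, adjusted p = 0.0004, and 0.0171 with an estimated correlation). The synapse list had 4 members higher and 1 lower, with SYT4 at 1.35 and SYN2 at 0.97 (median 0.18, adjusted p = 0.0084, and adjusted p = 0.108 with an estimated correlation). SYN2 did not pass on its other probe sets (−0.61, −0.46, 0.42 and 0.63).

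Neurotrophin and receptor genes had 3 of 21 members higher with GFP siRNA, including IGF1R (1.11) and RET (0.84), and none lower (median 0.20, camera adjusted p = 0.0339, adjusted p = 0.108 with an estimated correlation). Without untreated replicate 1 or 2 that list gave adjusted p = 0.0556 and 0.0697, with the array-set block 0.0511 and after median centring 0.0558. Of the fibroblast and substrate-adherent cell markers 4 of 32 rose, including LUM (2.73) and THY1 (1.03), and none fell (median 0.32, adjusted p = 0.011, adjusted p = 0.0678 without untreated replicate 1, and adjusted p = 0.191 with an estimated correlation). Ribosomal protein genes had a median of −0.19, with none past the test, RPL11 at −0.74 (adjusted p = 0.0752) and RPL3 at −0.77 (adjusted p = 0.159). The list gave adjusted p = 0.00535 (adjusted p = 0.771 with an estimated correlation). Oxidative phosphorylation genes had 2 members lower, NDUFS6 (−1.57) and NDUFV1 (−1.01), and a median of −0.11 (adjusted p = 0.0473, and adjusted p = 0.771 with an estimated correlation). These are the lists that differed by 0.55 and 0.57 between the array sets, and within the set of 8 their medians were 0.01 and 0.03. The ribosomal call was lost without GFP siRNA replicate 2 (adjusted p = 0.377, median −0.01) or untreated replicate 3 (0.0656), after quantile normalization (0.0886) and with fry (0.516). With the array-set block the oxidative phosphorylation list gave adjusted p = 0.0859, after median centring 0.0624, after quantile normalization 0.199 and with fry 0.516. The oxidative phosphorylation call was also lost without GFP siRNA replicate 1 (0.378) or 2 (0.314) or untreated replicate 2 (0.231) or 3 (0.198).

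The other lists did not pass camera at its preset correlation between GFP siRNA and untreated cells. Fry passed the neural progenitor list (adjusted p = 0.0238), and camera with the replicate block the MYCN and MYC targets (0.0314). In the neural progenitor list 3 of 26 members fell, HES6 (−2.01) and the differentiation inhibitors ID1 (−1.33) and ID3 (−0.92). LDHA (−1.44) and NOLC1 (−0.81) fell among the MYCN and MYC targets. LDHA was the 1 change in the hypoxia list, BCL2 (0.89) in the apoptosis list, CMPK2 (−1.32) in the interferon list, HSPB8 (1.12) in the heat shock list and GAP43 (0.64) in the Schwann and glial list. HSPB8 did not pass on its other probe set (0.15). The RB pathway list had 2 members higher and 2 lower, the sympathoadrenal list 3 and 1 and cholesterol synthesis 1 and 3. No p53 target, histone, blood and endothelial or housekeeping gene passed without a block, and with the replicate block 2 p53 targets rose and 2 fell, and 3 histone genes fell.

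The largest non-overlapping changes with GFP siRNA were rises in TNFRSF12A (4.27, SE 0.72), ITGB8 (3.86), MIR7-3HG (2.99) and HMOX1 (2.69), which breaks down haem, with DUSP6, STMN4, LUM and DCX above, and falls in IDH1-AS1 (−3.34), LDB3 (−3.19), ATL3 (−2.73), DOK4 (−2.60), TTLL1 (−2.56), MICALCL (−2.50), LSM4 (−2.47) and CCDC102A (−2.43). For MIR7-3HG 2 untreated arrays were at the floor, and for IDH1-AS1, LDB3 and ATL3 1 GFP array each, so these sizes depend on the floor. On another probe set ITGB8 (0.35), STMN4 (0.37), LUM (0.26), LDB3 (−1.92) and ATL3 (−0.51) did not pass. Of the falls, IDH1-AS1, LDB3, ATL3, DOK4, TTLL1 and LSM4 were genes on which the GFP arrays also stood apart from both knockdowns. So were EGR1 and HES6 above. DOK4 had a mean log2 signal of 8.53 with GFP siRNA, 11.13 in untreated cells, 10.59 with CCND1 and 10.91 with CDK4 siRNA. Limma called 613 of 13764 genes, 309 higher and 304 lower, and 311 at least 2-fold. After median centring 223 were higher and 191 lower. The array-set block gave 2781 genes, the replicate block 2762 and the set of 8 alone 2250. Without GFP siRNA replicate 2 the count was 308, without untreated replicate 2 it was 214, and without untreated replicate 3 it was 233. Of 42 genes named as called, 16 lost the call when some 1 array was left out (GAP43, CCND1, MIR7-3HG, LDB3, SLC7A1, CMPK2, E2F2, HSPB8, TYMS, ATL3, HES6, CCDC102A, POLA2, RET, ID3 and THY1).

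The last comparison asked which changes the CCND1 and CDK4 knockdowns shared. Genes called the same way in both numbered 856, of which 486 were higher in both and 370 lower, and 28 were called in opposite ways. Lists drawn independently would share 75.6 higher and 68 lower. The CDK4 signal was lower in both, at 37.2% of the control with CCND1 siRNA and 13.5% with CDK4 siRNA. The overlap is thus not between knockdowns that each lowered a different transcript alone. Because both knockdowns were set against the same GFP arrays, part of the overlap can come from those arrays. In 20 simulations with no effect in either knockdown the mean correlation of log2 fold changes across genes was 0.428, a value fixed by the group sizes. It therefore does not show how much of the observed 0.579 came from the shared arrays, and genes are not independent replicates. The simulated mean covariance was 0.08, against 0.311 observed, and the simulated mean count of genes called the same way was 0. The GFP arrays were then split between the comparisons, which left each with fewer control arrays. Over 6 splits the correlation was 0.236 to 0.436, the covariance 0.159 to 0.258 and the shared count 342 to 576.

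The shared genes were also set against untreated cells, a comparison chosen after the data were examined. Of the 486 genes higher in both knockdowns than with GFP siRNA, 154 were also called lower with GFP siRNA than in untreated cells, and 95 were called higher in both knockdowns than in untreated cells. Of the 370 lower in both, 66 were called higher with GFP siRNA than in untreated cells, and 144 were called lower in both than in untreated cells. The GFP arrays shared by these comparisons raise such overlaps, so they were split, 2 against the knockdowns and 2 against untreated cells, in 6 ways. Then 31 to 87 of 230 to 682 genes higher in both were called lower with GFP siRNA than in untreated cells (1.1 to 10.3 for independent lists), and 8 to 30 of 127 to 369 lower in both were called higher (0.7 to 5.1). Neuronal differentiation genes rose from untreated cells in each knockdown, 10 of 37 with none lower for CCND1 siRNA (median 0.66, adjusted p = 0.0564 with an estimated correlation) and 10 with 1 lower for CDK4 siRNA (median 0.52, adjusted p = 0.0997 with an estimated correlation). With GFP siRNA 10 of 37 rose from untreated cells as well, with none lower (median 0.57). Against GFP siRNA the list did not pass in either knockdown (camera adjusted p = 0.797 and 0.826), so the rise was not particular to them. DNA replication genes fell from untreated cells, 42 and 49 of 54 (medians −1.28 and −1.93, adjusted p = 0.00722 and 0.0035 with an estimated correlation).

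Tested as the mean of both knockdowns against GFP siRNA, 2423 of 13764 genes passed, 1243 higher and 1180 lower, and 1075 at least 2-fold. DNA replication genes had 42 of 54 members lower and none higher (median −1.05, adjusted p = 0.0156 with an estimated correlation), G2/M genes 50 of 59 lower (adjusted p = 0.0193 with an estimated correlation), and histone genes 7 of 10 higher (median 1.84, adjusted p = 0.0402 with an estimated correlation). The largest shared rises were CFAP95 (3.79), ABCA12 (3.77), H2BC4 (3.62, with 3 of the 4 GFP arrays at the floor), ATL3 (3.56, on which the GFP arrays stood apart) and PTPRN2 (3.49, with 2 at the floor). The largest shared falls were TNFRSF12A (−2.68), the origin recognition subunit ORC1 (−2.57), ZNF367 (−2.58) and the mitotic kinesin KIF23 (−2.55). TNFRSF12A had risen from untreated cells to GFP siRNA.

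Median centring moved the share of these genes that were higher from 51.3% to 37.8%. With the replicate block 4553 genes passed and 2047 were shared by both knockdowns, and with the array-set block 5140 and 2467. Without CCND1 siRNA replicate 3 the shared count was 517, and without replicate 4 it was 519.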

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

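The tests of splits, of the array sets, of the GFP siRNA group and of CDK4 in the CCND1 siRNA arrays were chosen after the results were seen, and the values of single arrays were looked at by a fixed rule.

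The 13 arrays fell into 2 sets that cut across the groups, and 6914 genes differed between them. The sets were defined by the deviations of these same arrays, which by itself raises that count. A difference in RNA integrity or labelling is a candidate explanation: the actin 3′ to 5′ ratio parted the sets with a two-sided exact permutation p of 0.000777, the smallest that 1287 choices of 5 arrays allow, but the GAPDH ratio did not (exact p = 0.502). A different growth state of the cells may also differ between sets, and the DNA replication genes were higher in the set of 8 by a median of 0.19 (camera adjusted p = 0.769), as were the MYCN and MYC targets by 0.33 (adjusted p = 0.041, and 0.513 with an estimated correlation). The bound for that last test was made stricter after its value was seen. The explanations cannot be told apart, since the actin ratio was 1 of the measures that showed the sets and no label gives a date or a batch.

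The GFP siRNA arrays stood apart from each of the 3 other groups in 66 genes that were higher and 154 that were lower, so that these genes enter every comparison with the control. The array sets are argued against as the whole cause. In the set of 8 alone, which holds 2 arrays of each group, 816 genes stood apart by the test. The 5 other arrays were looked at for direction only, without a test, and held 1 array of each group but GFP. There the GFP mean lay beyond all 3 other groups the same way in 91.7% of these genes, against 23.5% of all genes. The median of their smallest log2 differences there was 0.5. After median centring 58 such genes were higher and 106 lower (64.6% lower), and after quantile normalization 63 and 162. Lower genes stayed the more numerous, but median centring left fewer of them, so scaling may account for a part. The bound set for this test was also passed by the untreated (68.5% lower) and CDK4 siRNA (73% lower) groups without centring, so it cannot decide the question. Lowering of transcripts by the GFP siRNA itself may account for a part, but 78.2% of those at least 2-fold away were lower in the GFP group against 69.2% in the untreated, 79.7% in the CDK4 siRNA and 41.3% in the CCND1 siRNA group, and without transcript sequences no seed match could be searched, so this cannot be told apart from other effects of the control. A response of cells shared by both knockdowns and by untreated cells stays open and untested.

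CDK4 mRNA was lower in the CCND1 siRNA arrays, at 37.2% of the control. RNA of CDK4 siRNA samples mixed into them would need a share of 72.3%, which alone would bring a CCND1 signal of 1530, against 527 ± 27.6 (SD, n = 3) measured. The array sets are argued against as the whole cause, since the log2 fold change was −1.55 with the array-set block, and −1.81 and −1.34 within the sets. A hypothesis left untested is that CDK4 mRNA depends on cyclin D1, directly or through slower proliferation. An off-target effect of the CCND1 siRNA could not be tested without transcript sequences, so it stays open.

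Single arrays lay far from the other 3 of the GFP group for 12 of 140 named genes, where chance gives about 1 in 20. The figure for each is the gap to the nearest array over the group's range. On the log2 scale ALK was high in replicate 1 (7.09 against 6.32 to 6.45, ratio 0.838), and IRF1 low there (3.55 against 4.92 to 5.16, 0.856). In replicate 2, HSPB8 was high (7.70 against 7.07 to 7.12, 0.931), as were STIP1 (10.72 against 9.91 to 10.03, 0.848), THY1 (9.77 against 8.92 to 9.02, 0.891) and H2BC4 (3.08, with the others at the floor of 1.82, ratio 1). In replicate 3, DMD was low (6.50 against 6.71 to 6.72, 0.934), while KLF2 (8.23 against 7.67 to 7.73, 0.894), PTPRN2 (2.07 against 1.82 to 1.86, 0.843) and SLC7A11 (7.29 against 7.07 to 7.09, 0.911) were high. In replicate 4, SCUBE1 (4.31 against 2.59 to 2.82, 0.862) and TNFRSF4 (2.45, with the others at the floor of 1.82, ratio 1) were high.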

How the results depend on the processing

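The array-set block and the set of 8 arrays alone were chosen after the data were examined, and the other alternatives before. Counts below are for CCND1 with GFP, CDK4 with GFP, CCND1 with CDK4, GFP with untreated, the mean of both knockdowns with GFP, and genes shared by both knockdowns, in that order where 6 are given. The cause was not tested unless the construction of an alternative shows it. With the replicate block they were 3637, 4462, 3002, 2762, 4553 and 2047, with a random block 3315, 4114, 2659, 2119, 4188 and 1835, with the array-set block 4261, 5103, 3924, 2781, 5140 and 2467, and in the set of 8 alone 3609, 4208, 3392, 2250, 4199 and 2002. The added 2-fold condition left 888, 1505, 781, 311, 1075 and 433. Array weights gave 2864 for CCND1 with GFP, 2822 for CCND1 with CDK4, 1763 for GFP with untreated and 1569 shared. The mean of all probe sets gave 820 for CCND1 with CDK4, 326 for GFP with untreated and 566 shared. Fitting the compared groups alone gave 612 for CCND1 with CDK4 and 210 for GFP with untreated. Testing all probe sets gave 3855 for CDK4 with GFP and 3736 for the mean of both, with more features tested. The correlation of effects was 0.537 with no filter and 0.617 with the filter at the 60th percentile. The call of the DNA replication genes with CCND1 siRNA was lost with an estimated correlation (adjusted p = 0.056; median −0.72, which that choice cannot alter).

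Leaving out each array in turn gave 893 to 1587 genes for CCND1 with GFP, 1701 to 2357 for CDK4 with GFP, 718 to 965 for CCND1 with CDK4, 214 to 582 for GFP with untreated, 1709 to 2687 for the mean of both and 517 to 883 shared, with fewer arrays in each fit. The correlation ran from 0.531 to 0.624. DNA replication medians ran from −0.76 to −0.67 (CCND1 siRNA) and from −1.50 to −1.18 (CDK4 siRNA), and neuronal medians from 0.07 to 0.25 and from −0.06 to 0.07. In the set of 8 alone, medians for GFP siRNA with untreated cells turned to 0.009 (ribosomal) and 0.027 (oxidative phosphorylation). Between CCND1 and CDK4 siRNA the oxidative phosphorylation median ran from −0.35 to 0.012, turning without CCND1 siRNA replicate 1, and the ribosomal median from −0.19, turning without CDK4 siRNA replicate 2, to 0.192. Among gene lists 1932 alternative values kept the side of the threshold, 145 of them uncalled and without keeping direction, 94 lost the call, 58 gained one and 4 turned with a call on either side. Among named genes 3578 kept the side, 3 of them uncalled and without keeping direction, 370 lost the call, 37 gained one and 0 turned with a call. As detection calls were not used, the floor at signal 3.53 sets what can be read of dim probe sets.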

Other observations

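The counts of splits, and the genes that set groups apart, were looked at only after the comparisons were seen.

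Genes that differed from all other groups were sought for each group. CDK4 siRNA had the most, 152 higher and 410 lower. FN1, the matrix protein fibronectin, had a mean log2 signal of 6.67 there against 4.68 in untreated cells, 4.83 with GFP siRNA and 4.93 with CCND1 siRNA. IQGAP1, a scaffold of the actin cytoskeleton, had 6.44 against 8.84, 8.98 and 8.70, and PNMT had 2.47 against 4.97, 4.90 and 5.16. With CCND1 siRNA 81 genes were higher and 84 lower. The hormone gene STC1 had 8.46 against 6.30 in untreated cells, 6.11 with GFP siRNA and 5.70 with CDK4 siRNA, and the kinase gene HIPK2 had 8.48 against 6.93, 5.62 and 6.77. The DNA repair gene NBN had 7.67 against 8.91, 9.04 and 8.94. These genes were chosen after their values were seen.

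Untreated cells had 28 genes higher and 61 lower than each transfected group. Among the higher were UNG, which removes uracil from DNA (9.12 against 7.36 with GFP, 7.48 with CCND1 and 7.27 with CDK4 siRNA), and UHRF1, which maintains DNA methylation (10.43 against 9.48, 8.55 and 7.89). Among the lower were the sodium channel SCN2A (3.08 against 5.43, 5.19 and 6.31), the peptide gene CARTPT (4.90 against 7.33, 6.59 and 7.29) and the serotonin receptor HTR2B (5.16 against 6.96, 9.05 and 8.95). GFP siRNA arrays had TNFRSF19 (8.45 against 6.77 in untreated cells, 6.68 with CCND1 and 6.48 with CDK4 siRNA) and the cadherin CDH11 (9.55 against 8.09, 8.04 and 7.86) among their higher genes, and HES6 (4.75 against 6.76, 7.47 and 7.30) among their lower ones.

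Other splits of the same arrays into groups of the same sizes were fitted for each count. For CDK4 with GFP siRNA only the real split of 35 gave as many as 2509 genes, and the highest other gave 0. With the array-set block the real split gave 5103 and the highest other 2142. For CCND1 with GFP siRNA 2 of 35 splits gave as many as 1582, and chance is not excluded by this count. The other split, with 1591 genes, set GFP siRNA replicates 1 and 2 and CCND1 siRNA replicate 1 against the rest, which is the array set of 5, and with the array-set block the real split gave 4261 and the highest other 1766. For GFP siRNA with untreated cells 2 of 35 splits gave as many as 613, and the other, with 2178, again followed the array sets, a structure of the arrays larger than the comparison. With the array-set block the real split gave 2781 and the highest other 1158. These blocked counts favour the real split, since the sets were defined by deviations from the real groups. Among the 8 splits that part all 3 pairs of equal number, the real one gave the most for CCND1 with GFP siRNA (highest other 0) and for CDK4 with GFP siRNA (highest other 0), but 8 splits are too few for a share under 0.05. The replicate block gave 3637 and 4462 for them.

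For CCND1 with CDK4 siRNA there are 10 splits, too few for a share under 0.05, with 1298 genes in the real one and 0 in the highest other. For the mean of both knockdowns 1 of 100 drawn splits, the real one, gave 2423 genes, with 1726 in the highest other. For shared genes 1 of 100 gave 856, with 635 in the highest other. These draws ignore the replicate numbers and array sets and exchange the GFP arrays with the others. They argue against no difference among the 3 groups. They cannot tell changes shared by the knockdowns from GFP arrays that stand apart. With labels exchanged only within replicate numbers, 100 of the 144 possible labellings were used, and the real one gave the most for both counts (highest other 1553 and 585). Those highest others were among the 3 that keep the GFP arrays together, and the 96 that move a GFP array gave at most 497 and 0. The median change of the DNA replication genes was largest in the real split of 35 for CCND1 siRNA (0.718 in size, highest other 0.608) and for CDK4 siRNA (1.342, highest other 1.076). For the neuronal differentiation genes 14 of 35 splits gave a median as large as 0.13 with CCND1 siRNA (highest other 0.322), and 30 of 35 one as large as 0.018 with CDK4 siRNA (highest other 0.252), so chance is not excluded for either.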
